A study of Homo sapiens with 24 samples.

How the data were processed

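The series measured polyadenylated RNA in stratum corneum stripped from the forehead of 12 healthy volunteers with the SmartSticker and Dsquame platforms, in 24 libraries. Per the labels' protocols, the tapes of a site were pooled in a tube, RNA was extracted with magnetic beads on an automated instrument, and libraries were made with a low-input kit from polyadenylated RNA. Each library has its own table of 60660 genes. The authors deposited estimated counts per gene, which need not be whole (63.3% of the values above 0 were exactly whole, with no tolerance), together with TPM, a length-corrected share of transcripts, and the length and effective length of each gene. The aligner, the quantification program, its version and the annotation release are not given in the sources used here. The submitters' processing notes name the human genome builds hg38 and GRCh38. No molecular identifiers are named in the labels, so reads amplified from 1 molecule are not known to be merged, and intervals and floors cover counting error only.

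Genes were named through a table of Ensembl identifiers, which held a symbol for 60419 of the 60660 identifiers. Gene type, chromosome and position came from GENCODE release 29 on GRCh38, which held 58429 of them, and 0.119% of the reads lay on identifiers without a type there. Coordinates are 1-based and from that release. The estimated counts were rounded to whole numbers before the count models and thinning, and 0 columns were left unmatched to a sample. Whether the counting used strand is not given in the sources used here. Levels of genes with close copies or processed pseudogenes, such as LCE, SPRR and keratin genes, ribosomal protein genes and mitochondrial genes with nuclear copies, are uncertain to the extent that reads were split between copies. No 2 libraries held the same values. As a check of the labels, the 2 libraries of a volunteer were compared in sex-linked transcripts, and they differed in 1 of 12 volunteers, so a mislabelled pair, on which the paired results would partly rest, is not excluded.

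Groups and volunteer numbers came from the sample titles. The numbers pair the libraries because, per the labels, both libraries of a number came from the same volunteer. As a check, each SmartSticker library's deviation from its platform's mean was correlated with that of the Dsquame library of the same volunteer, which gave -0.351 to 0.595. The main tests were unpaired, and tests with the volunteer as a block were the alternative. Scalar measures were compared with two-sided permutation tests of the difference of means (100000 resamples) and with an exact test over the 4096 swaps of platform within volunteers, whose smallest p is 0.000488. These 6 measures (library total, detected genes, detected genes at equal depth, inflammatory genes detected, share of the 10 most abundant genes and mitochondrial share) were adjusted together by the Benjamini-Hochberg method. A gene counted as detected with at least 10 estimated reads. The floor of 3 reads corresponds to 1.33 CPM (counts per 1000000 reads) in the smallest library. For equal depth, every library was thinned at random without replacement to the smallest total. Intervals of differences are 95% intervals from the 12 paired differences. The Wilson 95% interval of the mitochondrial protein share ran from 11.38 to 11.47% in the smallest library.

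Genes were compared with edgeR 4.0.16 in R 4.3.3, with TMM factors, its default low-count filter by platform, and the quasi-likelihood test with robust dispersion, over 14580 genes. The threshold was a Benjamini-Hochberg adjusted p of 0.05. The common biological coefficient of variation was 1.06. The TMM factor of the Dsquame library of volunteer 1 was 0.0785, while the others lay between 0.535 and 1.90. Fitted folds, their p values and the volunteer counts of single genes used these factors. Printed CPM means, SDs and medians were taken over library totals without them, so they can differ from the fitted folds in size and direction. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, for lists with at least 5 tested members. The 24 lists cover cornified envelope, late cornified envelope, barrier lipid synthesis, suprabasal keratins and desmosomes, basal keratinocytes, proliferation, wound and stress keratinocytes, antimicrobial genes, desquamation, sebaceous gland, hair follicle, sweat gland, melanocyte, Langerhans and antigen presenting cells, T and NK cells, fibroblast, endothelial, blood cell, inflammatory biomarkers, immediate early and heat shock, housekeeping, ribosomal protein, mitochondrially encoded protein and nuclear retained RNA. Correlations between libraries used log2 CPM with a prior count of 2 over the tested genes. Other tools were DESeq2 1.42.0, Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and statsmodels 0.14.6.

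The samples, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names the 8 genes with the smallest p in each direction among protein-coding and long non-coding genes past the threshold that moved the same way in at least 10 of 12 volunteers. Where under 3 passed in a direction, it names the 3 with the smallest p as not past the threshold, here taken among genes of the same direction in at least 10 volunteers. From each list it names the 2 members with the smallest p if any passed, and otherwise the most abundant tested members, and it adds the 10 most abundant genes of each platform and ACTB, GAPDH and B2M. Genes on the Y chromosome, XIST and TSIX are never named. The result of 1 gene that the rule names is not reported here. The alternatives covered pairing, normalization, count tool, low-count filter, detection limit, depth, mitochondrial genes and each volunteer left out. Fits without volunteers 1 and 3, without volunteers 1, 3, 5 and 12, without the Dsquame library of volunteer 1 alone and with library totals, and the tests of read shares, were chosen after the data were seen. The counts over other splits of the libraries were run before their predictions were written down.

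The gene model was tested on simulated data with the means, library sizes and dispersions of the 24 libraries, in which 200 of 14580 genes were changed between the platforms. The changed genes were chosen from the more abundant ones, so recovery of the scarcest genes was not tested. Of 50 genes per fold the model recovered 4% of those changed 2-fold, 36% at 4-fold, 66% at 8-fold and 94% at 16-fold, with 1 unchanged gene called. Each gene was drawn independently there. The 1 unchanged gene called therefore says nothing about false calls from variation shared between genes or from 1 unusual library. In simulated data with 1 list changed 4-fold, that list was called in the right direction.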

Results

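Stratum corneum, the dead outer layer of the epidermis, was collected from the forehead of 12 healthy volunteers with 2 adhesive tape-stripping platforms, SmartSticker and Dsquame, and its polyadenylated RNA was sequenced. Each volunteer gave 1 library per platform, so the 24 libraries formed 12 pairs. The design names the quality of the reads, their mapping efficiency and the number of detected genes as the points on which the platforms were to be compared. Only the last can be taken from the gene tables, and read quality and mapping were not analysed here. From volunteer 1 to volunteer 12, the SmartSticker libraries held 18610433, 33838264, 16624280, 20993295, 21078467, 20730327, 18854492, 20245545, 18969469, 17460526, 22720865 and 11726640 estimated reads. The Dsquame libraries held 2261436, 25757477, 5813346, 42640643, 13316290, 17754109, 25722593, 15779811, 18153209, 23256446, 21914611 and 19117706 in the same order. SmartSticker totals were higher in 8 of 12 volunteers, with a geometric mean 1.24 times that of Dsquame, a difference within the spread between libraries (two-sided permutation test on log2 totals, p = 0.413). The log2 difference of 0.31 was 0.06 without volunteer 1 and -0.08 without volunteers 1 and 3.

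Both platforms recovered the transcripts of keratinocytes in their last steps of differentiation. MALAT1, a nuclear long non-coding RNA, was the most abundant gene on both, at 46610 ± 7513 CPM (counts per 1000000 reads) on SmartSticker and 51980 ± 19840 on Dsquame (SD, n = 12 each). Next on SmartSticker came ASPRV1, the protease that processes profilaggrin, at 24130 ± 11260 against 27670 ± 12480 CPM, and KRTDAP, a secreted keratinocyte differentiation protein, at 21570 ± 9350 against 24490 ± 8772. CTSV, the cathepsin that acts in desquamation, reached 21380 ± 10540 and 23470 ± 11420, and SPRR4, a cross-linked protein of the cornified envelope, 18340 ± 8582 and 26090 ± 16220. CST6, a cysteine protease inhibitor, was at 12430 ± 7108 and 23020 ± 15440, and SPINK5, the inhibitor of kallikrein proteases, at 10290 ± 2548 and 10350 ± 3943. The alarmin S100A7 was at 10850 ± 4859 and 8514 ± 6069. The mitochondrial ribosomal RNA MT-RNR2 also ranked in the top 10 of both, at 13840 ± 23230 and 32460 ± 52090. FLG (8180 ± 6611 and 6994 ± 2091) was in the top 10 of SmartSticker alone, and the related FLG2 (7529 ± 3278 and 8870 ± 3096) in that of Dsquame alone. None of these genes passed the threshold between the platforms (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; the smallest adjusted p was 0.198, for MT-RNR2). Among common reference genes, ACTB was at 4693 ± 1745 and 4085 ± 872.7 CPM (adjusted p = 0.475), GAPDH at 661 ± 351.5 and 428.5 ± 426.1 (adjusted p = 0.933), and B2M at 2826 ± 2467 and 1227 ± 1257 (adjusted p = 0.975). The adjusted p values belong to fitted log2 folds with TMM factors, which had the opposite direction to these means: -1.25, -0.51 and -0.29.

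The number of detected genes, the measure named in the design, was 16049 ± 2609 per SmartSticker library and 12791 ± 5002 per Dsquame library, counting genes with at least 10 estimated reads (SD, n = 12 each). SmartSticker gave more genes in 10 of 12 volunteers, with a mean difference of 3257 genes and a 95% interval of the paired difference from -186 to 6700. The permutation test gave p = 0.0558 and, with the 6 measures of this kind adjusted together, 0.0837. The difference was 1498.4 genes without volunteers 1 and 3 (p = 0.271). The libraries were then thinned to the total of the smallest one, 2261404 reads. At that depth, SmartSticker libraries held 9946 ± 1350 genes and Dsquame libraries 8238 ± 2572, higher on SmartSticker in 9 of 12 volunteers (p = 0.0472, adjusted p = 0.0837, paired exact test p = 0.0659). The Dsquame libraries of volunteers 1 and 3 held 2303 and 4749 genes at equal depth, while the lowest of the other 22 libraries held 7396. Without these volunteers the difference was 656.5 genes (p = 0.308).

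Fewer genes were shared by all Dsquame libraries. In all 12 SmartSticker libraries, 7150 genes had at least 10 reads, against 1509 in all 12 Dsquame libraries and 1489 in all 24. Without volunteers 1 and 3 these numbers were 7240 and 6594. In at least 6 libraries of a platform, 16333 genes were seen on SmartSticker and 13116 on Dsquame. Of these, 12971 were common to both platforms. At equal depth, 4631 genes had at least 10 reads in all 12 SmartSticker libraries and 1262 in all 12 Dsquame libraries. Without volunteers 1 and 3 the equal-depth numbers were 4697 and 4448. In at least 6 libraries of a platform they were 10218 and 8735 over all volunteers.

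**Figure D1:**
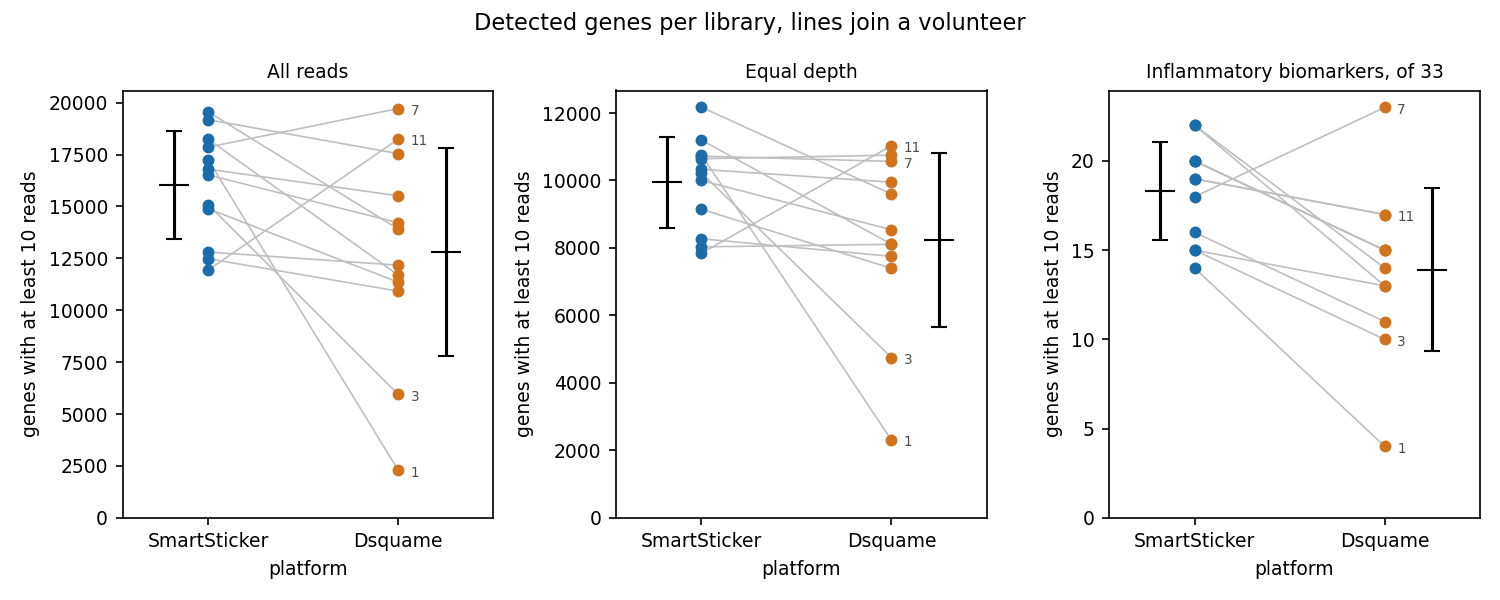
Number of genes with at least 10 estimated reads per library, with all reads (left), after thinning every library to the smallest total (middle), and for the 33 inflammatory biomarkers (right). Each point is 1 library, grey lines join the 2 libraries of a volunteer, black marks give mean and SD (n = 12), and volunteers 1, 3, 7 and 11 are numbered; the Dsquame libraries of volunteers 1 and 3 lie lowest at equal depth, with 2303 and 4749 genes.

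Genes used as biomarkers of inflammatory skin disease were detected in larger number on SmartSticker, a difference that missed the threshold in the unpaired main test once adjusted. Of the 33 genes on the list, 18.3 ± 2.74 had at least 10 reads per SmartSticker library and 13.9 ± 4.56 per Dsquame library, and 11 of 12 volunteers gave more on SmartSticker (p = 0.0091, paired exact test p = 0.00635). Over the 6 measures the adjusted p of the unpaired test was 0.0546, and the paired p values were not adjusted together. With a limit of 1 read the difference was 3.25 genes (p = 0.0649). It was 3.17 genes at equal depth (unadjusted permutation p = 0.00762) and 3.8 without volunteers 1 and 3 (unadjusted p = 0.0111). With 1 volunteer left out the largest unadjusted p was 0.0238, without volunteer 9. On the list, 22 genes were detected in more SmartSticker than Dsquame libraries and 5 in more Dsquame libraries. As examples with wide gaps, chosen after their values were seen, the cytokine genes TSLP and IL23A were detected in 8 and 9 SmartSticker libraries against 2 and 4 Dsquame libraries, TNF in 7 against 2, and the chemokine gene CCL20 in 10 against 4. Others lay close, such as CXCL8 in 8 against 7 and IL36G in 9 against 9, or were detected in more Dsquame libraries, such as CCL17 in 7 against 8. Cytokines that lymphocytes make, IL17A, IL22, IL13 and IFNG, had 10 reads in no more than 1 library of either platform. The chemokine CCL22 was at 2664 ± 4819 CPM on SmartSticker and 543.2 ± 465 on Dsquame, with medians of 533 and 516.8 (log2 fold 1.90 ± 0.70 SE, adjusted p = 0.240). IL18, a cytokine that keratinocytes store, was at 1109 ± 478.5 and 1127 ± 588.9. No member of the list passed the threshold, whether adjusted over all genes tested or adjusted over the list alone, and the list as a whole did not pass it either (adjusted p = 0.401). Without volunteers 1 and 3 it passed towards higher levels on SmartSticker (adjusted p = 0.0377), but not with an estimated correlation (0.611).

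A few genes took a larger share of the reads on Dsquame, a difference that missed the threshold in the unpaired main test. The 10 most abundant genes held 25.8 ± 8.22% of the reads on Dsquame and 19.9 ± 5.68% on SmartSticker, with the higher share on Dsquame in 10 of 12 volunteers (permutation p = 0.0528, adjusted p = 0.0837). In the paired exact test p was 0.0469, and without volunteers 1 and 3 the difference went from -5.87 to -3.10 percentage points (p = 0.303). The 13 protein-coding mitochondrial genes held 2.16 ± 2.28% on SmartSticker and 3.62 ± 5.16% on Dsquame (p = 0.405), a difference of -1.46 percentage points that became 0.806 without volunteers 1 and 3 (p = 0.427). All genes of the mitochondrial chromosome together held 26.63% of the reads of the Dsquame library of volunteer 1, 32.97% of that of volunteer 3, 11.5% of that of volunteer 5 and 18.4% of the SmartSticker library of volunteer 12. Among the 12 Dsquame libraries, the log2 mitochondrial share ran against the number of genes at equal depth (Pearson r = -0.734, p = 0.00952, adjusted over 4 relations 0.028; Spearman rho = -0.329, p = 0.297). That relation rests on volunteers 1 and 3, since r was -0.104 without them. Among the SmartSticker libraries r was -0.293 (p = 0.36) and rho -0.063 (p = 0.85). The number of reads went with the number of genes at equal depth on Dsquame (r = 0.70, p = 0.014; rho = 0.804, p = 0.00245; r = 0.934 without volunteers 1 and 4), but not on SmartSticker (r = 0.146, p = 0.658; rho = -0.14, p = 0.669). Whether the platforms differ in these relations was not tested.

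**Figure D2:**
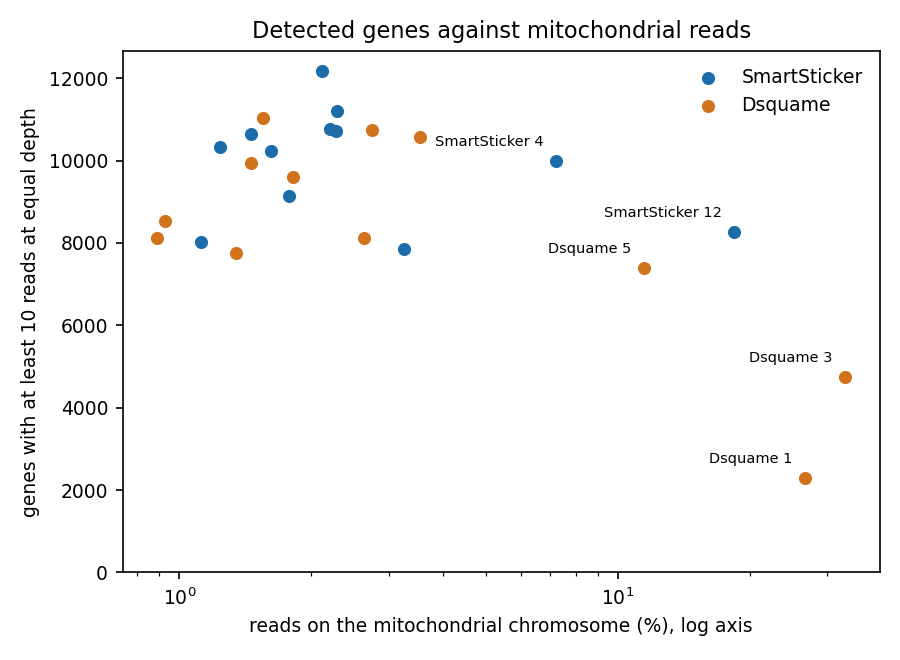
Genes with at least 10 reads at equal depth (vertical axis) against the percentage of reads on the mitochondrial chromosome (horizontal log axis), 1 point per library, coloured by platform. Libraries with high mitochondrial shares are named by platform and volunteer; the Dsquame libraries of volunteers 1 and 3, at 26.63% and 32.97%, lie below all others.

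Of 14580 genes tested between the platforms, 226 passed an adjusted p of 0.05, and 225 of them were lower on SmartSticker. Among the protein-coding and long non-coding genes with a symbol, 27 of these were lower in at least 10 of 12 volunteers. Genes of other types were not counted in the 27. The median of all 225 genes was lower in 7 volunteers. The 8 named by the rule, all from the 27, were RRP1, which acts in ribosome biogenesis, the transcription elongation factor ELL, the prefoldin chaperone subunit PFDN2, the endocytosis adaptor HIP1R, BBLN, CCSER2, the deubiquitinase MINDY2 and EEPD1. Their median levels, taken over library totals, lay much closer than the fitted folds, which also used TMM factors. PFDN2 (chromosome 1, 161100556 to 161118111) had medians of 20.5 CPM on SmartSticker and 25.3 on Dsquame, with 1926 in the Dsquame library of volunteer 1 (log2 fold -7.12 ± 1.51 SE, adjusted p = 0.0444). HIP1R (chromosome 12, 122834453 to 122862960) had medians of 43.2 and 67.7, with 3680 in that library, and CCSER2 (chromosome 10, 84328558 to 84518521) medians of 104.6 and 140.9, with 2296. RRP1 (chromosome 21, 43789513 to 43805293) did not have its high value there: it was at 0.442 in that library, with medians of 1.17 and 3.51 and a lower level on SmartSticker in 11 volunteers (log2 fold -4.12 ± 0.85 SE, adjusted p = 0.0444). The 1 gene that was higher on SmartSticker, named after its value was seen, was the pseudogene CECR7, at 2.38 ± 1.80 against 0.309 ± 0.421 CPM (log2 fold 2.90 ± 0.68 SE, adjusted p = 0.0444, higher in 11 of 12 volunteers).

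No protein-coding or long non-coding gene passed as higher on SmartSticker. Those of consistent direction with the smallest p values were 3 genes that did not pass the threshold. ENTR1, an endosome-associated protein, was at 1.77 ± 0.859 against 0.214 ± 0.504 CPM (adjusted p = 0.0613), and GLUD1, the mitochondrial glutamate dehydrogenase, at 18.7 ± 9.90 against 5.25 ± 4.55 (adjusted p = 0.0709). The gene for carboxypeptidase M was at 57.7 ± 110.1 against 10.6 ± 9.98 (adjusted p = 0.103).

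The Dsquame library of volunteer 1 stood apart in these genes. The 225 genes took 26.6% of its reads, against a median of 1.54% and at most 1.86% in the other Dsquame libraries and a median of 1.43% on SmartSticker, and 219 of them had their highest level there. The 225 genes were called in the same data with this library included, so their high share in it partly follows from that choice. Without that library 0 genes passed (edgeR; 731 at an unadjusted p under 0.05), and with volunteer as a block in the model 0 passed as well (521 unadjusted, against 1354 in the unpaired model). DESeq2 called 33 genes, 5 higher and 28 lower, of which 8 were among the 226. With library totals in place of normalization factors the median log2 fold of all tested genes moved from 0.01 to 0.33, and 0 genes passed (428 unadjusted).

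Of 20 gene lists with at least 5 tested members, 10 passed the competitive test (camera with a preset correlation of 0.01), 1 towards higher and 9 towards lower levels on SmartSticker, and 0 passed with an estimated correlation. Without volunteers 1 and 3, 2 of the 10 still passed, the desquamation and the antigen presenting cell lists, and with an estimated correlation 0 did. Genes of the cornified envelope were lower as a list (29 tested, median log2 fold -0.72, adjusted p = 4.8e-05; adjusted p = 0.504 with an estimated correlation). LORICRIN, the main protein of the envelope, passed by itself (98.2 ± 109.4 against 605.8 ± 1648 CPM, medians 82.9 and 122.3, with 5831 in the Dsquame library of volunteer 1, adjusted p = 0.0444). Involucrin, IVL, was at 193.5 ± 113.5 against 346 ± 346.9 (adjusted p = 0.0684). In this list 1 gene was lower over all genes tested and 2 adjusted over the list alone. The list held 9.06 ± 3.33% of the reads on SmartSticker and 10.7 ± 3.68% on Dsquame, lower on SmartSticker in 10 of 12 volunteers (permutation p = 0.266). The late cornified envelope genes (16 tested, median -0.97, adjusted p = 0.00924; adjusted p = 0.613 with an estimated correlation) had 0 members past the threshold and 2 adjusted over the list alone. Their share of reads was 0.663 ± 0.530% against 0.803 ± 0.7499%. The call was lost without the Dsquame library of volunteer 1 (adjusted p = 0.132), and the direction turned to higher without volunteers 1, 3, 5 and 12 (0.0545). LCE1C was at 992.5 ± 651.4 against 1785 ± 1929, and LCE3D at 2075 ± 2107 against 2193 ± 3003 CPM.

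Proteases and inhibitors of desquamation were lower as a list on SmartSticker (22 tested, median log2 fold -0.38, adjusted p = 0.000286; adjusted p = 0.504 with an estimated correlation), with 0 single members past the threshold, over all genes tested or adjusted over the list alone. They held 8.56 ± 3.28% of the reads on SmartSticker and 10.4 ± 4.20% on Dsquame. Without volunteers 1 and 3 this list still passed (adjusted p = 0.0175; 0.611 with an estimated correlation), while the cornified envelope list did not (0.0642). Suprabasal keratins and desmosome genes were lower too (14 tested, median -0.60, adjusted p = 0.00924; adjusted p = 0.504 with an estimated correlation). The desmosomal plakophilin PKP3 (20.6 ± 7.78 against 90.4 ± 216.6 CPM, medians 18.7 and 24.4, with 775.6 in the Dsquame library of volunteer 1, adjusted p = 0.0444) and plakoglobin, JUP (207 ± 86.9 against 331.6 ± 464.6, medians 202.1 and 197.3, with 1794 in the same library, adjusted p = 0.0464), were its 2 members past the threshold, and 5 passed adjusted over the list alone. The share of reads on this list was slightly higher on SmartSticker, within the spread between libraries (0.909 ± 0.279% against 0.830 ± 0.233%, in 6 of 12 volunteers, permutation p = 0.453), and the call was lost without volunteer 1 (adjusted p = 0.0669) and without volunteers 1 and 3 (0.144). Wound and stress keratins and alarmins (11 tested, median -0.32, adjusted p = 0.0112; adjusted p = 0.504 with an estimated correlation) had 0 members past it, with KRT17 at 3698 ± 2121 against 4519 ± 2498. Their share of reads was also higher on SmartSticker (2.46 ± 0.806% against 2.30 ± 1.06%, in 7 of 12 volunteers, permutation p = 0.684), and the call was lost without volunteers 1 and 3 (adjusted p = 0.219).

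Langerhans and other antigen presenting cell genes were the list that was higher on SmartSticker (13 tested, median log2 fold 1.71, adjusted p = 0.0247; adjusted p = 0.613 with an estimated correlation), with 0 single members past the threshold. The invariant chain gene CD74 was at 4945 ± 8756 CPM on SmartSticker and 1276 ± 2874 on Dsquame, with medians of 386.5 and 261.9, and HLA-DRA at 1126 ± 2012 and 294.5 ± 822.3, with medians of 83.0 and 16.7. The list's share of reads was 0.831 ± 1.49% against 0.214 ± 0.497% (permutation p = 0.180), higher on SmartSticker in 8 of 12 volunteers, and it reached 4.92% in the SmartSticker library of volunteer 10 and 1.77% in the Dsquame library of volunteer 7. Without volunteers 1 and 3 the list passed at an adjusted p of 1.3e-05 (0.611 with an estimated correlation), and with library totals in place of normalization factors it did not pass (0.0789). It also did not pass without volunteer 2, 4, 9, 10, 11 or 12, with adjusted p values from 0.0506 to 0.376. With volunteer as a block, 12 lists passed, the 10 above together with basal keratinocytes (higher, adjusted p = 0.0132) and barrier lipid synthesis (lower, adjusted p = 0.0112). With an estimated correlation in this fit 0 lists passed, and these 2 gave 0.536 each.

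Mitochondrially encoded protein genes had the smallest p of the lists (13 tested, median log2 fold -3.10, adjusted p = 1.0e-05; adjusted p = 0.504 with an estimated correlation). In this list 0 genes passed over all genes tested and 13 adjusted over the list alone, with MT-CO2 at 4217 ± 4726 against 7287 ± 10740 CPM and medians of 2515 and 2527. Without volunteers 1 and 3 the list's direction turned to higher and it did not pass (adjusted p = 0.250), and without volunteers 1, 3, 5 and 12 it passed as higher on SmartSticker (0.0170; 0.763 with an estimated correlation). Cytosolic ribosomal protein genes were lower (79 tested, median -0.19, adjusted p = 0.00135; adjusted p = 0.613 with an estimated correlation), with 5 members past the threshold and 25 adjusted over the list alone. RPL11 was at 201.8 ± 126.9 against 312.1 ± 510.7 CPM (medians 180.9 and 179.2, with 1904 in the Dsquame library of volunteer 1, adjusted p = 0.0473), lower in 6 of 12 volunteers, and the list turned to higher without volunteers 1 and 3 (adjusted p = 0.144). The share of reads on the ribosomal list was higher on SmartSticker in 9 of 12 volunteers (1.93 ± 1.01% against 1.67 ± 0.9498%, permutation p = 0.521). Immediate early and heat shock genes were lower (16 tested, median -0.39, adjusted p = 0.0113; adjusted p = 0.510 with an estimated correlation), with JUND the 1 member past the threshold (10.98 ± 4.30 against 47.4 ± 135.3, medians 11.03 and 6.56, with 476.7 in the Dsquame library of volunteer 1, adjusted p = 0.0444) and 2 adjusted over the list alone, a list call lost without volunteers 1 and 3 (adjusted p = 0.350). Nuclear retained RNAs, led by MALAT1 and NEAT1 (1475 ± 466.5 against 1560 ± 657.3), were lower as well (6 tested, median -0.49, adjusted p = 0.0247; adjusted p = 0.440 with an estimated correlation), with 0 members past the threshold and 1 adjusted over the list alone, and their call was lost without volunteers 1 and 3 as well (0.254).

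The other 10 tested lists, the inflammatory list among them, did not pass. Basal keratinocyte genes (adjusted p = 0.0563) were led by KRT14, at 2190 ± 1924 against 2146 ± 2523 CPM, and KRT15, at 2043 ± 2563 against 729.6 ± 1030 with a higher level on SmartSticker in 10 of 12 volunteers. Proliferation genes had an adjusted p of 0.0652 (0.0383 without volunteers 1 and 3, where an estimated correlation gave 0.611), with PCNA at 29.03 ± 22.5 against 17.6 ± 14.6 and TOP2A at 11.4 ± 16.1 against 3.97 ± 7.85. Barrier lipid synthesis gave 0.0896, antimicrobial genes 0.230, eccrine and apocrine sweat gland 0.404, hair follicle 0.567, sebaceous gland 0.827, housekeeping 0.915 and fibroblast and dermal matrix 0.965. Over all genes tested, COL6A3 of the fibroblast list passed (13.7 ± 6.04 against 26.5 ± 33.2 CPM, medians 11.6 and 12.5, with 128.2 in the Dsquame library of volunteer 1, adjusted p = 0.0460), although the list's median was positive (0.15) and its mean negative (-0.28). Adjusted over the list alone, 1 gene each passed as lower in the barrier lipid, hair follicle, fibroblast and housekeeping lists. Melanocyte, T and NK cell, endothelial and blood cell lists had under 5 tested members and no list test over all libraries. Without volunteers 1, 3, 5 and 12 the T and NK cell list had enough members and passed as higher on SmartSticker (adjusted p = 0.00183; 0.520 with an estimated correlation). Their shares of reads were 0.0229 ± 0.0153% against 0.0126 ± 0.00504% for melanocyte genes, 0.00822 ± 0.0136% against 0.00326 ± 0.00710% for T and NK cell genes, 0.00117 ± 0.00127% against 0.00029 ± 0.000341% for endothelial genes and 0.000581 ± 0.000424% against 0.000948 ± 0.00102% for blood cell genes. Of the read shares of all 24 lists, a test added after the data were seen, the smallest p was 0.00928 for melanocyte genes in the unpaired test (0.223 adjusted over the 24) and 0.00391 for endothelial genes in the paired exact test (0.0938 adjusted over the 24). MITF, at 157.3 ± 67.5 against 110.6 ± 45.6 CPM, made up most of the melanocyte share on both platforms.

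**Figure D3:**
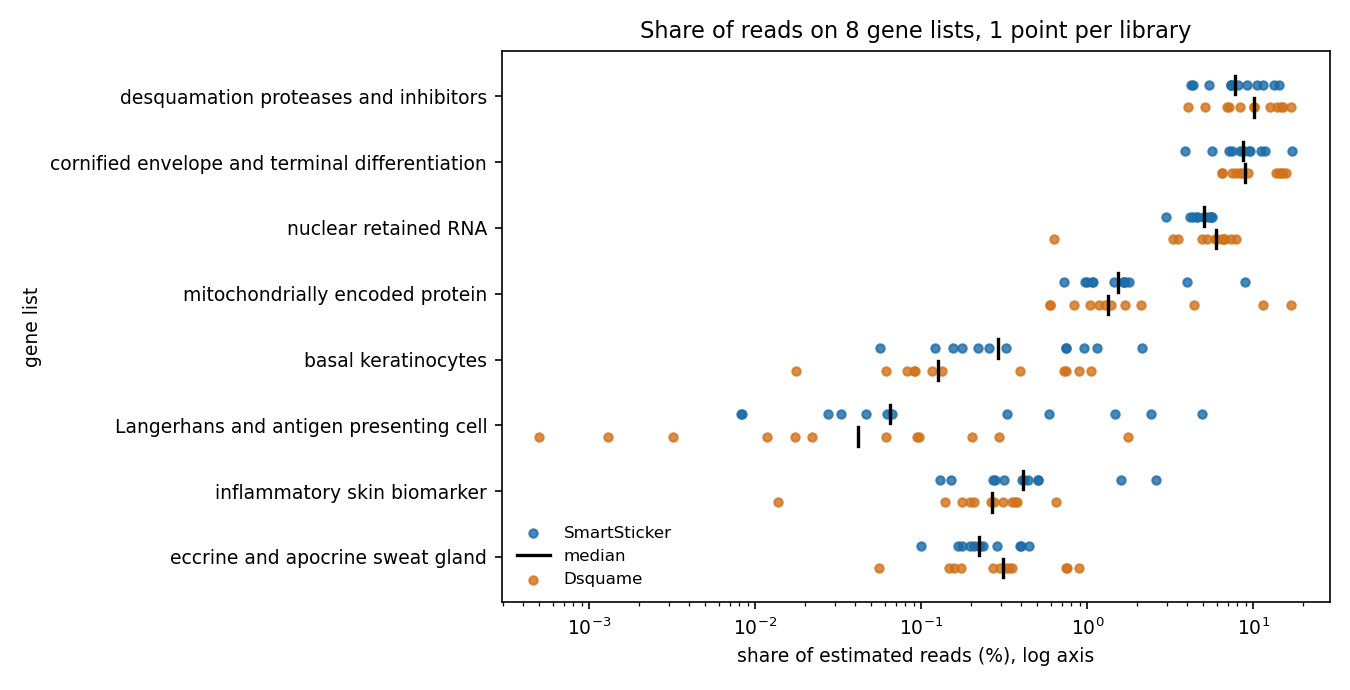
Percentage of estimated reads on 8 of the gene lists (horizontal log axis), 1 point per library coloured by platform, with a black bar at the median of the 12 libraries. The Langerhans and antigen presenting cell list spreads widest, up to 4.92% in 1 SmartSticker library, and the mitochondrial list reaches 16.9% in 1 Dsquame library.

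Profiles of different volunteers were compared within each platform. The mean Pearson correlation of log2 CPM, taken across genes between libraries of different volunteers, was 0.779 on SmartSticker and 0.672 on Dsquame, a difference of 0.107 that did not pass (exact test swapping platforms within volunteers, p = 0.0869) and was 0.0490 without volunteers 1 and 3 (p = 0.352). Between platforms, the 2 libraries of a volunteer correlated at 0.731 ± 0.112 (range 0.570 to 0.944), against 0.719 for libraries of different volunteers. After each platform's mean was removed per gene, the correlation was 0.0791 within volunteers and 0.0035 between them, a difference of 0.0756 (permutation p = 0.230). Over the 2000 most abundant genes that difference was 0.210 (p = 0.0415), and without volunteer 11 it was 0.125 over all tested genes (p = 0.0142).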

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

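Alternatives that leave out libraries other than 1 volunteer at a time, those with library totals, and the estimated correlation combined with another change were chosen after the data were seen. The count of genes between the platforms, 226, was 0 with the replicate block by volunteer, with voom and quality weights, without a low-count filter (49584 genes tested), without mitochondrial genes, with library totals, without the Dsquame library of volunteer 1, without volunteers 1 and 3 (also with the block), without volunteers 1, 3, 5 and 12, and without each volunteer in turn (0 to 0; 618 to 1755 at an unadjusted p under 0.05). It was 33 with DESeq2, and 335, 337, 227 and 294 with RLE factors, upper quartile factors, a filter of 10 reads in 12 libraries and thinned libraries, of which 226, 226, 225 and 184 genes were among the 226. The count of lists, 10, was 0 with an estimated correlation (also with the block, without volunteers 1 and 3, and without volunteers 1, 3, 5 and 12), 4 without volunteers 1 and 3, 6 without volunteers 1, 3, 5 and 12, 12 with the block, and 4 (without volunteer 1) to 14 (without volunteer 8) with 1 volunteer left out. The cornified envelope, desquamation and mitochondrial lists passed in 12 of 12 such fits, the Langerhans list in 6. The gene calls lay close under the threshold and shared adjusted values. In the main edgeR test RRP1 and LORICRIN had unadjusted p values of 4.5e-05 and 0.00029 and the same adjusted p of 0.0444. A small change in the p values can therefore drop many gene calls at once. Apart from fewer libraries or genes, other causes were not tested.

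Passing in this paragraph means an unadjusted p under 0.05. The difference in genes at equal depth, 1708.3, passed only in that sense (permutation p = 0.0472, adjusted p = 0.0837). It lost that call in the paired test (p = 0.0659), without volunteers 1 and 3 (656.5) and without volunteers 1, 3, 5 and 12 (536.8). With 1 volunteer left out it ran from 1094.9 (without volunteer 1, p = 0.135) to 2153.3. Leaving out volunteer 3, 4, 5, 6, 9, 10 or 12 also gave p above 0.05. The difference in all detected genes passed at a TPM of at least 1 (2518.5, p = 0.0390) and without volunteer 7 or 11, in a range from 2193.6 (without volunteer 1) to 4126.7, and was 1498.4 (p = 0.271) without volunteers 1 and 3 and 1351.4 (p = 0.378) without volunteers 1, 3, 5 and 12. Inflammatory genes detected differed by 3.25 with 1 read (permutation p = 0.0649), and kept an unadjusted p under 0.05 in the other settings. The share of the 10 most abundant genes, -5.87, passed in the paired test and without volunteer 10 or 11, in a range from -7.52 to -4.23, and was -3.10 without volunteers 1 and 3 and -2.55 without volunteers 1, 3, 5 and 12. The similarity within platforms passed without volunteer 11 or 12, in a range from 0.0796 to 0.137, and was 0.0490 without volunteers 1 and 3. The difference between the same and other volunteers passed over 2000 genes (0.210) and without volunteer 11, in a range from 0.0314 to 0.125. Library size and mitochondrial share never passed, and both changed sign without volunteers 1 and 3 (log2 -0.08 and 0.806). At an unadjusted p of 0.05, the paired test changed no other call of these measures, and its p values were not adjusted over them.

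Of the 14 named genes past the threshold, 3 changed sign in some setting, to values that did not pass, as did 23 of the 50 others (6 genes with the block). The log2 fold of JUND was 0.12 with DESeq2, 0.0814 with voom, 0.20 without the Dsquame library of volunteer 1, 0.36 without volunteers 1 and 3 (0.31 with the block), 0.52 without volunteers 1, 3, 5 and 12, and -6.08 to 0.23 with 1 volunteer left out. RPL11 was at 0.0463 without volunteers 1 and 3 (0.0452 with the block) and 0.0779 without volunteers 1, 3, 5 and 12, where LORICRIN was at 0.18. In other settings that left out more than 1 volunteer or changed the method, single genes kept their side of the threshold in 738 comparisons. They lost their call in 129, lost it with a change of sign in 10 and gained one in 7. The 738 include the 50 genes that had no call to lose, so all lost calls fall on the 14 genes past the threshold. Leaving out volunteers with under 1000000 reads gave no value of its own, since no library was that small.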

Other observations

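The tests in this part were chosen after the platform results were seen, and those on abundant genes, missing genes, matched random lists and volunteer tracking before their own results were. Genes listed as markers of cells below or beside the cornified layer were detected on both platforms. Whether their transcripts came from such cells was not tested. Some were scarce, with median CPM on SmartSticker and Dsquame of 1.26 and 0.30 for IL7R, 0.848 and 0.129 for TRAC, and 2.72 and 0.114 for TOP2A. All 15 proliferation genes and all 8 melanocyte genes reached 10 reads in more SmartSticker than Dsquame libraries, as did 12 of 14 Langerhans and antigen presenting cell genes, 11 of 14 T and NK cell genes and 11 of 12 fibroblast genes, and 0 genes of these lists did so in more Dsquame libraries. Of 8 endothelial genes, 5 were in more SmartSticker and 2 in more Dsquame libraries, and of 9 blood cell genes 2 and 2. These counts were not tested, and they go with the larger number of detected genes of any kind on SmartSticker (3362 in at least 6 libraries there alone, against 145 on Dsquame alone). At equal depth the numbers of genes on 1 platform alone were 1643 and 160. MKI67, a marker of dividing cells, was detected in 6 SmartSticker and 3 Dsquame libraries, the Langerhans cell gene CD207 in 8 and 6, and the pigment gene TYRP1 in 7 and 2. Hair follicle genes were divided, with 8 of 22 in more SmartSticker and 7 in more Dsquame libraries. Of the sebaceous gland genes, SCD and PLIN2 were abundant on both platforms (267.9 ± 95.0 against 256.4 ± 206.1 CPM, and 242 ± 101.2 against 243.5 ± 156.4), while AWAT2 and MC5R were detected in 0 libraries.

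By rank correlation, the sweat gland list was the one whose read share came closest to following the volunteer on both platforms, through 1 gene, MUCL1, which made up 96.01% of that share on SmartSticker and 98.07% on Dsquame. Across 12 volunteers, the log2 share on SmartSticker and that on Dsquame had a Pearson r of 0.741 (p = 0.00605) and a Spearman rho of 0.811 (p = 0.00215), with r = 0.724 without volunteers 4 and 6. Over the 24 lists the adjusted p were 0.145 and 0.0516. In a split made after these values were seen, MUCL1 alone had r = 0.715 (p = 0.0091) and rho = 0.769 (p = 0.00481), and the other 11 genes r = -0.177 (p = 0.580) and rho = -0.287 (p = 0.367), so the relation was not seen in the rest of the list. Volunteer 4 had the largest share on both, 0.442% and 0.892%. The hypothesis that the volunteer sets list shares on both platforms had 0 of 24 lists past the threshold, while 17 of 24 rank correlations were positive and the median rho was 0.294. It stays open, since with 12 pairs a missed threshold excludes nothing, although the prediction written beforehand had taken it so.

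The genes lower on SmartSticker may come from 1 library. Without the Dsquame library of volunteer 1 the count went from 226 to 0, although 0 genes also passed without any other single volunteer, with 1099 to 1755 genes at an unadjusted p under 0.05 against 731 without that library. A difference in depth is argued against as the whole cause, since with every library at the smallest total 294 genes passed, 184 of them among the 226. Chance cannot be excluded: of 100 splits of the 24 libraries, the real one counted, 15 called as many genes (highest of the others 342) and 16 as many lists (highest 14, against 10), and of 100 splits that part every pair, again with the real one, 18 and 17 did (highest 427 and 13). A platform difference of smaller size remains open, as the simulated test, with genes drawn independently, recovered 36% of 4-fold changes among more abundant genes.

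The Dsquame libraries of volunteers 1 and 3 had few detected genes. Depth is argued against, since both of the 2 lay below the lowest of the other 22 libraries at equal depth (2303 and 4749 against 7396). So are genes abundant across the libraries taking the reads, since both of the 2 stayed below the others with mitochondrial genes and the 100 most abundant genes removed (2191 and 4992 against 7767). Those 100 genes were chosen by their mean share over all 24 libraries. Genes abundant in 1 of the 2 libraries alone may have stayed in, so the test cannot decide that case. Few RNA molecules sampled stays open: of the genes for which the other libraries predicted at least 20 reads, 13.5% and 19.02% had no read, more in both of the 2 than in any other library (at most 10.7%), but missing genes partly restate few detected genes, and the library with fewer genes missed the smaller share. Whether the platform, the site or the extraction brought this about was not tested.

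A further hypothesis was that SmartSticker took up more of the living layers. Over 85 genes of 7 lists of living or deeper cells against 69 genes of 3 cornified layer lists, the mean log2 ratio was 0.71 ± 1.93 higher on SmartSticker (SD, n = 12; 8 volunteers above 0; exact sign-flip p = 0.226), and without volunteers 1 and 3 it was 0.83 (p = 0.2285), so the difference did not exceed the spread between volunteers. Leaving out 1 volunteer gave 0.44 to 1.07 (p = 0.424 to 0.0488). Loss of scarce transcripts on Dsquame may contribute, as random lists matched in abundance gave a mean of 0.27, but 0 of 1000 reached the real ratio. The excess over them was 0.44 ± 1.10 (p = 0.189), within the spread between volunteers, so neither explanation is decided.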
